A study of Homo sapiens with 12 samples.

How the data were processed

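Messenger RNA was sequenced in 12 libraries of the human bladder cancer lines T24 and RT4, with 3 libraries labelled shFTO and 3 labelled shNC per line. Per the labels' protocols, total RNA was taken with Trizol, poly(A) RNA was selected, and paired-end reads of 150 bases were sequenced on an Illumina X plus instrument. Per the submitters' processing notes, reads were trimmed with fastp 0.20.0, aligned with STAR 2.7.9a and counted with featureCounts 2.0. Genome builds mm39, GRCh38 and hg38 are all named there, without a role for each. The strand setting, the annotation release and the handling of reads with several positions are not given in the sources used here. The deposited table holds counts for 43557 genes, 13012 of them named by an Ensembl ID, and 99.5% of the symbols stand in the gene name table. RefSeq GRCh38.p14 positions were found for 30064 genes.

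Groups follow the labels, and the mapping was fixed before the data were examined, as were the comparisons, tests, 40 gene lists, the rule for named genes and most alternatives. Labels were kept although FTO was higher in the RT4 libraries labelled shFTO. The labels also carry a batch number from 1 to 3 equal to the replicate number, so each batch holds 1 library of each group. That number is what pairs shFTO with shNC libraries. As a check of pairing, residuals of genes at 10 CPM or more were correlated between shFTO and shNC libraries of a line. Libraries with the same number had r = 0.101, -0.036 and 0.019 in T24 and -0.098, -0.022 and -0.02 in RT4, and only T24 replicate 1 correlated best with its own number. No methods text states a block, so none was used in the fit reported.

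Counts were scaled with TMM and filtered with filterByExpr by group, which left 23070 genes. One edgeR 4.0.16 quasi-likelihood fit (robust, 4 groups, 8 residual degrees of freedom, common biological coefficient of variation 0.077) gave the knockdown contrast in each line, their difference (T24 minus RT4), and the contrast of the controls. P-values were adjusted by Benjamini-Hochberg over all tested genes and called under 0.05. Levels are TMM-scaled CPM, and log2 changes are edgeR's fitted values with its prior count of 0.125. An SE is the absolute log2 change divided by the square root of its quasi-likelihood F statistic. It is given for FTO only, because it can fall below counting error where a group is near 0 counts. The pairing check used log2 CPM with a prior count of 2. Where a group had 0 counts in all its libraries, a bound is given that sets 3 counts over the group. With 1 to 3 counts the ratio and its 95% counting interval are given instead. Overlaps of calls were compared with independent lists and by one-sided Fisher exact tests, and shared calls also by Fisher exact tests in either direction. FTO also had an exact permutation test.

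Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, over the 39 lists with at least 5 tested members, with an estimated correlation and fry as alternatives. Of 1119 list entries, 13 matched no gene in the table. The erythroid marker list had 1 tested member and was not tested. Medians were recomputed with members at 0 counts set to their bound.

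Named genes follow a fixed rule. FTO is always named. For each line the rule takes the 10 largest rises and the 10 largest falls among called genes that have a symbol that is not a clone, locus or small RNA identifier, a mean of at least 1 CPM in that line, the same direction in all 3 same-numbered pairs, and no overlap between the groups' values. For shared changes it takes 10 genes each way with the largest smaller change of both lines, and for the interaction and the controls 5 each way. For lists it takes up to 4 members with the smallest p. XIST and Y-linked genes were left out of all named genes, and some genes that the rule takes are not reported here.

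Alternatives fixed beforehand were RLE and upper-quartile scaling, no low-count filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, each line fitted alone, the batch number as a block within each line, leaving out each library in turn, and a 2-fold threshold. Thinning every library to the smallest total, and library totals as the only scaling for FTO, were added after the data were seen. Every other split of the libraries into groups of the same sizes was run for counts of calls. Where both lines were split, 40 splits were used, the real one and random draws. Library similarity, a measure chosen after the data were seen, is Pearson r of log2(CPM + 1) over 16200 genes with a mean of at least 1 CPM. Sampling noise between replicates was checked on genes with at least 50 counts per pair. It gave chi-squared per degree of freedom from 5.44 to 16.35, above the 1 of the same library sequenced again.

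Precision was tested on simulated data, with 200 genes changed per comparison among 21080. In T24, 62.7%, 83.6% and 97.0% of genes changed 1.5-, 2- and 4-fold were recovered, and in RT4 70.1%, 94.0% and 100.0%. Among calls, 5.8% in T24 and 4.9% in RT4 were unchanged genes. A list planted in the T24 simulation was called, and 0 random lists were. In the data 78% of genes were called in T24 and 78.6% in RT4, far more than were changed in the simulation. The rates therefore describe a setting with few changed genes of at most 4-fold, and cannot stand for the fits of these data. Depth ranged from 31291047 to 102798895 counts per library. Other tools were R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No sequence reads were used here.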

Results

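Poly(A)-selected RNA was sequenced from 12 libraries of the bladder cancer cell lines T24 and RT4, as labelled. T24 is a line from a high-grade urothelial carcinoma and RT4 a line from a well-differentiated papillary tumour. Within each line, 3 libraries were labelled shFTO (knockdown of FTO, an RNA demethylase that acts on N6-methyladenosine, m6A) and 3 were labelled shNC (control). Total counts per library, in replicate order, were 32703357, 31291047 and 43791909 for T24 shNC and 54553356, 34281703 and 41309338 for T24 shFTO. For RT4 they were 38761639, 102798895 and 84029429 for shNC and 41412793, 38972182 and 42451196 for shFTO. Levels are TMM-scaled CPM, given as mean ± SD over 3 libraries per group unless another measure is named. Calls rest on edgeR's quasi-likelihood test with Benjamini-Hochberg (BH) adjustment over 23070 genes. The labels do not say that the replicates came from separate cultures, so p-values measure the spread between these libraries. Intervals and bounds on folds cover counting error only.

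FTO (chromosome 16, 53703963 to 54121941, RefSeq GRCh38.p14) was examined first because it is the targeted gene. In the libraries labelled T24 it was 35.2 ± 1.25 CPM in shNC and 25.5 ± 1.09 CPM in shFTO, 72.4% of the control level (63.9% on library totals). The log2 change was -0.46 (SE 0.049, edgeR BH-adjusted p = 1.93e-07), and within batches 1, 2 and 3 it was -0.45, -0.47 and -0.48. In the libraries labelled RT4, FTO was higher in shFTO than in shNC, 68.9 ± 3.29 against 46.2 ± 1.01 CPM, or 149.1% of the control level (123.9% on library totals). The log2 change was 0.58 (SE 0.045, edgeR BH-adjusted p = 4.19e-09), and within batches it was 0.64, 0.61 and 0.48. With library totals as the only scaling it was 0.31 (edgeR BH-adjusted p = 7.18e-06). The changes differed between the lines by -1.04 on the log2 scale (SE 0.067, edgeR BH-adjusted p = 2.75e-10). FTO counts per library ranged from 862 to 5140. The median absolute log2 change of all tested genes was 1.06 in T24 and 1.04 in RT4, above that of FTO in both. Of 9 tested neighbours of FTO on chromosome 16, 2 rose and 7 fell in T24 (median -0.89, mean 0.17, camera BH-adjusted p = 0.339) and 5 rose and 3 fell in RT4 (median 0.49, camera BH-adjusted p = 0.258). Their changes differed between the lines, 0 higher and 7 lower in T24 (median -0.74, camera BH-adjusted p = 0.0361, adjusted p = 0.137 with an estimated correlation, and 0.0539 with a filter of 1 CPM in 3 libraries). Counts adjusted over the list alone were the same. An exact two-sided permutation test of FTO gave p = 0.1 in each line, the smallest that 3 libraries against 3 allow. Because FTO went against the RT4 label, groups are named as labelled throughout, and every direction in RT4 is that of the libraries labelled shFTO relative to those labelled shNC.

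**Figure D1:**
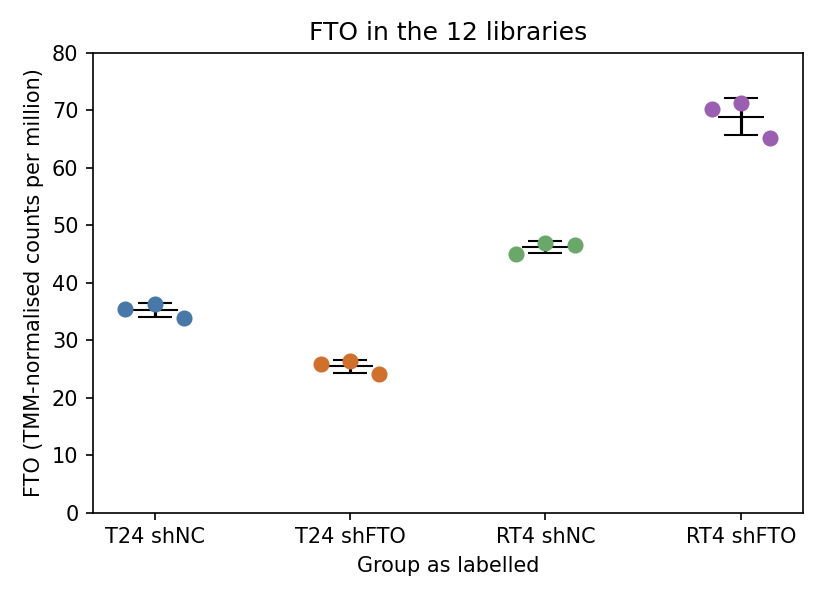
FTO in TMM-normalised CPM (y axis) for the 3 libraries of each labelled group (points), with group mean and SD (black bars). The T24 shFTO libraries average 25.5 CPM against 35.2 in T24 shNC, and the RT4 shFTO libraries average 68.9 CPM against 46.2 in RT4 shNC.

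Library profiles separated by labelled group, not by labelled line. Across 16200 genes, log2(CPM + 1) values of replicates correlated with Pearson r from 0.996 to 0.998. Between the T24 groups the mean r over 9 library pairs was 0.706, and between the RT4 groups it was 0.761. The highest mean r between groups was 0.781, for T24 shNC against RT4 shFTO, and the controls of both lines stood at 0.729. These correlations are across genes, which are not independent replicates. Mitochondrially encoded transcripts took 7.7% to 8.1% of counts in T24 shFTO against 5.3% to 5.7% in T24 shNC, and 7.0% to 7.5% in RT4 shFTO against 4.7% to 5.7% in RT4 shNC, so this share was higher under the shFTO label in both lines. The 10 most abundant genes took 8.9% to 9.2% of counts in T24 shFTO against 6.4% to 6.6% in T24 shNC, and 7.8% to 8.1% in RT4 shFTO against 7.9% to 8.3% in RT4 shNC.

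**Figure D2:**
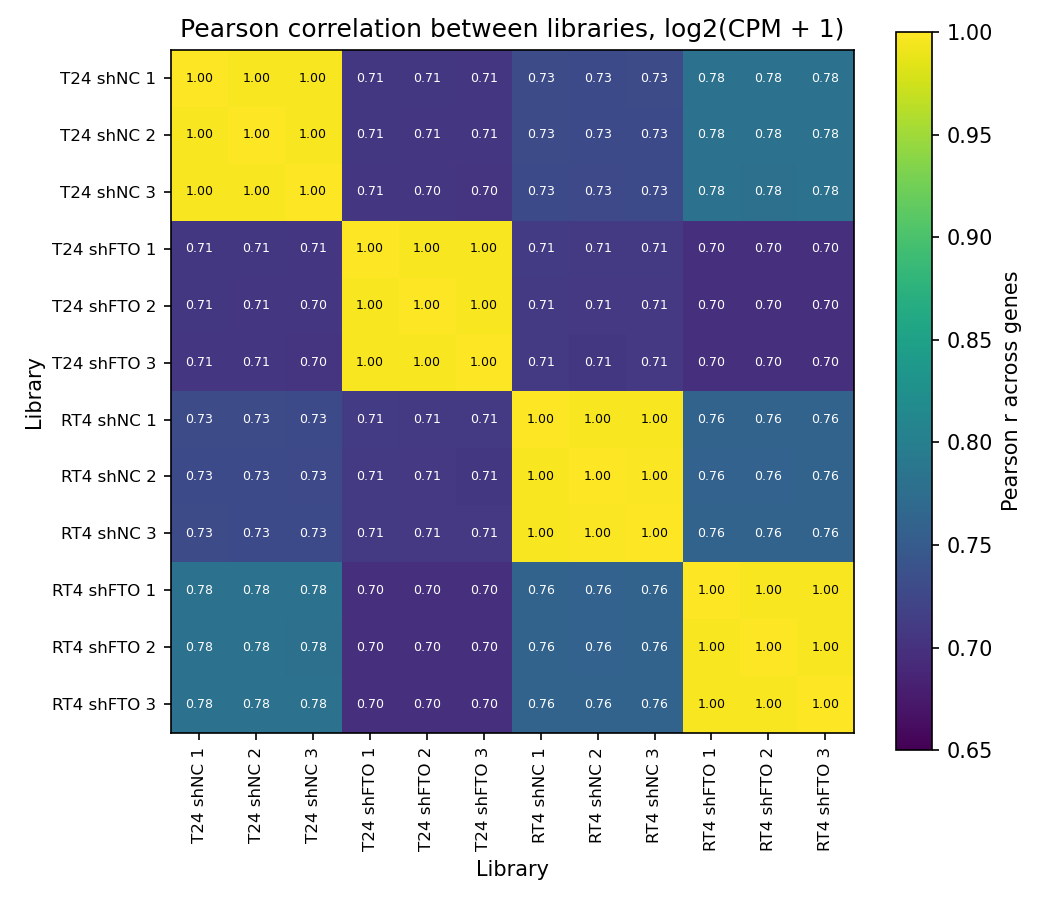
Pearson r across 16200 genes between each pair of the 12 libraries, on log2(CPM + 1) values (colour and printed value, both axes list libraries by labelled group and replicate). Replicates stand at 0.996 or above, and the mean r is 0.706 between the T24 groups and 0.761 between the RT4 groups.

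The T24 comparison asks which genes differed between libraries labelled shFTO and shNC. Genes for secreted plasma proteins were among those that rose most. ALB (serum albumin) went from 0.0844 ± 0.0254 to 10700 ± 414 CPM (log2 change 16.87), and APOB (the structural protein of low-density lipoprotein) from 0.0428 ± 0.0742 to 6008 ± 118 CPM (16.75). Counts were 0 in all 3 shNC libraries for GPC3 (a cell-surface proteoglycan), ASGR2 (an asialoglycoprotein receptor subunit), PROX1 (a homeobox transcription factor), KRT23 (a keratin), and APOH, ORM1 and APOA1 (plasma proteins). GPC3 reached 648 ± 10 CPM in shFTO, at least 25000-fold higher, and for ASGR2, PROX1 and KRT23 the rise was at least 13250-, 12510- and 11200-fold. APOH, ORM1 and APOA1 were at least 9442-, 9115- and 8658-fold higher. These bounds set 3 counts over the group at 0. Among these rises the highest edgeR BH-adjusted p was 9.41e-10, for APOB.

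The largest falls in the libraries labelled T24 shFTO ended at 0 counts in all 3 libraries. MUC16 (the mucin that carries the CA125 antigen) fell from 432 ± 15.2 CPM, at least 17630-fold lower. HK1 (hexokinase 1, which phosphorylates glucose) fell from 349 ± 13.7 CPM (at least 14380-fold lower), TNS4 (a focal adhesion protein) from 299 ± 8.88 CPM (at least 12280-fold), and WNT5A (a secreted Wnt ligand) from 174 ± 4.23 CPM (at least 7119-fold). UGT1A7 (a glucuronosyltransferase), RSPO3 (a Wnt signal enhancer), PXDN (a matrix peroxidase), RNF182, IGFL2-AS1 and KCNK1 (a potassium channel) also fell, by bounds between 5148- and 16820-fold. Among these 10 genes the highest edgeR BH-adjusted p was 1.04e-07, for UGT1A7. UGT1A7 shares exons with other UGT1A genes, and IGFL2-AS1 is named as antisense where the strand setting of the counting is not known, so their counts are uncertain. In all, 18006 of 23070 genes (78.0%) were called, 8584 up and 9422 down, and 11242 of them changed at least 2-fold. The 3 values of each group did not overlap for 79.6% of genes, where chance gives 10%. Each batch held 1 library per group, so no test within a batch was possible.

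Of 39 fixed lists tested with camera at a preset correlation of 0.01, 13 were called in T24 (6 up, 7 down). With an estimated correlation camera called 0 at an adjusted p under 0.05 and 6 at an unadjusted p under 0.05, and fry called 39. Interferon-stimulated genes had the smallest p. Of 38 tested members 37 fell and 1 rose, the same counts as when adjusted over the list alone, with a median log2 change of -6.73 (-5.77 with members at 0 counts set to their bound). OASL, an antiviral gene, fell from 394 ± 3.49 to 0.0720 ± 0.00957 CPM. IFIT1 and IFIT2, which restrict viral translation, and BST2 (tetherin) changed by -9.93, -9.32 and -9.57 on the log2 scale. The camera BH-adjusted p was 7.44e-16, and the adjusted p was 0.175 with an estimated correlation. Antigen presentation genes followed the same direction, with 19 of 22 down and 1 up, and adjusted over the list alone also 19 and 1 (median -2.85, camera BH-adjusted p = 3.93e-07, adjusted p = 0.175 with an estimated correlation). HLA-B and HLA-C (class I molecules), TAP1 (a peptide transporter) and NLRC5 (the class I transactivator) changed by -5.28, -3.44, -6.07 and -6.32.

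NRF2 target genes, which serve redox defence, fell for 23 of 27 members and rose for 4, as they did adjusted over the list alone (median -1.99, camera BH-adjusted p = 2.6e-08, adjusted p = 0.202 with an estimated correlation). AKR1C2 went from 990 ± 15.4 to 2.91 ± 0.420 CPM, AKR1C1 changed by -4.89, and NQO1 (a quinone reductase) changed by -3.07. AKR1C1 and AKR1C2 are near copies that can share reads. In glycolysis and hypoxia, 28 of 36 fell and 5 rose, and adjusted over the list alone the counts were again 28 and 5 (median -1.28, camera BH-adjusted p = 6.19e-06, adjusted p = 0.175 with an estimated correlation). PFKP (a phosphofructokinase) and SLC2A1 (the glucose transporter GLUT1) changed by -7.93 and -3.38, while HK2 rose by 3.12. Basal and squamous genes fell for 18 of 21, with 2 up, equal to the counts adjusted over the list alone (median -8.21, or -5.72 with members at 0 at their bound, camera BH-adjusted p = 2.48e-05, adjusted p = 0.175 with an estimated correlation). LAMB3 (a laminin chain of epithelial basement membranes) changed by -5.61, and CD44 (a hyaluronan receptor) went from 351 ± 12.7 to 0.0261 ± 0.0452 CPM.

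Replication-dependent histone genes fell for 22 of 25, with 1 up, and adjusted over the list alone also 22 and 1 (median -3.25, camera BH-adjusted p = 3.52e-05, adjusted p = 0.175 with an estimated correlation). Their mRNAs mostly lack poly(A) tails, and the libraries were poly(A)-selected. H1-2 went from 42.9 ± 1.64 to 2.08 ± 0.208 CPM. Extracellular matrix and integrin genes fell for 23 of 39 and rose for 13, the same adjusted over the list alone (median -2.11, or -2.04 at the bounds, camera BH-adjusted p = 0.0328, adjusted p = 0.366 with an estimated correlation). This call was lost with the batch number as a block (adjusted p = 0.164), with upper-quartile scaling (0.0551), after thinning to the smallest library (0.0568), and without RT4 shNC replicate 1 (0.061) or 2 (0.0512). COL7A1 (the anchoring fibril collagen) went from 1379 ± 42.2 to 8.55 ± 0.709 CPM, and ITGA3 changed by -6.88.

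Epithelial junction genes rose for 19 of 29 in T24 and fell for 7, as adjusted over the list alone (median 2.24, camera BH-adjusted p = 0.00496, adjusted p = 0.366 with an estimated correlation). CLDN1 (a tight junction claudin) went from 3.56 ± 0.184 to 666 ± 14.7 CPM and EPCAM (an epithelial adhesion molecule) from 14.2 ± 0.286 to 377 ± 19.5 CPM, while PKP3 (a desmosome protein) changed by -4.93. The m6A writers, erasers and readers rose for 16 of 24 and fell for 4, the same adjusted over the list alone (median 0.40, camera BH-adjusted p = 0.0201, adjusted p = 0.584 with an estimated correlation). IGF2BP2 and IGF2BP1, which bind m6A-modified mRNA, changed by 4.47 and 2.84, and VIRMA, a scaffold of the methyltransferase complex, by 1.07. Cytosolic ribosomal protein genes rose for 34 of 52 and fell for 7 (median 0.53, camera BH-adjusted p = 0.00496, adjusted p = 0.75 with an estimated correlation), MYC-driven nucleolar genes rose for 29 of 38 and fell for 7 (median 0.39, camera BH-adjusted p = 0.00362, adjusted p = 0.584 with an estimated correlation), and mitosis genes rose for 24 of 40 and fell for 8 (median 0.32, camera BH-adjusted p = 0.0201, adjusted p = 0.584 with an estimated correlation). For the ATF4 list 20 of 34 rose and 12 fell (median 0.47, camera BH-adjusted p = 0.0376, adjusted p = 0.584 with an estimated correlation). In these 4 lists the counts adjusted over the list alone were the same. The ATF4 call was lost with the batch number as a block (camera adjusted p = 0.0966), after thinning (0.0568) and without RT4 shNC replicate 2 (0.0501). With T24 fitted alone the m6A, mitosis, MYC and ATF4 calls were lost (camera adjusted p = 0.0706, 0.118, 0.0786 and 0.0566), and with a filter of 1 CPM in 3 libraries the m6A, mitosis and ATF4 calls were (0.0665, 0.0697 and 0.0541). Upper-quartile scaling shifts the median of all genes by -0.105 in T24 and -0.107 in RT4 relative to TMM, and no called list changed the sign of its median under another scaling.

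The series title names stemness-associated phenotypes, and that list did not pass in T24. Of 28 members 17 rose and 10 fell, also adjusted over the list alone (median 0.73, camera BH-adjusted p = 0.0937). SOX9 (a progenitor transcription factor) went from 0.822 ± 0.119 to 90.6 ± 2.01 CPM and ALDH1A1 (a retinal dehydrogenase) from 0.0341 ± 0.0307 to 919 ± 51.1 CPM, while CD44 changed by -13.29 and ENG (endoglin) by -7.36 on the log2 scale. Mesenchymal and EMT genes (11 up, 17 down of 32, camera BH-adjusted p = 0.124), luminal urothelial genes (10 up, 10 down of 21, 0.849) and replication genes (18 up, 10 down of 40, 0.554) did not pass either, with the same counts adjusted over the list alone. With T24 fitted alone, camera called the stemness list (adjusted p = 0.0019) up and the EMT list (adjusted p = 4.86e-05) down. The stemness list was also called without a low-count filter (0.0278), and the EMT list with a filter of 1 CPM in 3 libraries (0.0484). The luminal list had a median of -0.20 but a mean of 1.14, with KRT7 changed by -10.24 and FGFR3 by 3.99. Markers of fibroblasts, leukocytes, endothelium and neurons had camera BH-adjusted p of 0.976, 0.584, 0.849 and 0.661. Of 23 tested hepatocyte markers, a list chosen after the values were seen, 21 were at 10 CPM or more in T24 shFTO and 1 in T24 shNC, with summed levels of 32720 and 147 CPM.

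The RT4 comparison asks the same question for the libraries labelled RT4, where FTO itself was higher under the shFTO label. Collagen and matrix genes were among the largest rises. COL1A2 (a type I collagen chain) went from 0.0195 ± 0.0184 to 6499 ± 147 CPM (log2 change 17.87) and COL5A1 (a type V collagen chain) from 0.0226 ± 0.0228 to 1541 ± 27.2 CPM (15.59). CHI3L1 (a secreted chitinase-like glycoprotein) had 0 counts in shNC and 1027 ± 19.1 CPM in shFTO, at least 83480-fold higher. PKP1 (a desmosome protein), ANGPTL2 (a secreted angiopoietin-like protein), IGFBP5 (an insulin-like growth factor binding protein), CDH13 (a cadherin), RARRES2 (chemerin), UGT1A10 (a glucuronosyltransferase) and FENDRR (a long non-coding RNA) also rose from 0 counts, at least 12190- to 31960-fold. UGT1A10 shares exons with other UGT1A genes, and FENDRR lies beside an oppositely transcribed gene while the strand setting is not known, so both counts are uncertain. Among these 10 genes the highest edgeR BH-adjusted p was 2.52e-14.

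The largest falls in RT4 ended at 0 counts in the libraries labelled shFTO. MAGEA4 (a cancer-testis antigen) fell from 580 ± 10.1 CPM (at least 21520-fold lower) and UCHL1 (a deubiquitinase of neurons) from 490 ± 13.4 CPM (at least 18260-fold). LIN28B (an RNA-binding protein that blocks let-7 maturation) fell from 112 ± 1.58 CPM (at least 4137-fold), and CDKN2B (the CDK inhibitor p15) from 108 ± 3.58 CPM (at least 4030-fold). TDRD9 and GTSF1, which act in germline transposon silencing, PRAME (a cancer-testis antigen), MUC15, MYEF2 and KCTD15 fell by bounds between 2216- and 5403-fold, and the highest edgeR BH-adjusted p of the 10 was 1.15e-07. In all, 18124 of 23070 genes (78.6%) were called, 8907 up and 9217 down, 11073 of them at least 2-fold. Values of the groups did not overlap for 79.9% of genes, where chance gives 10%.

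**Figure D3:**
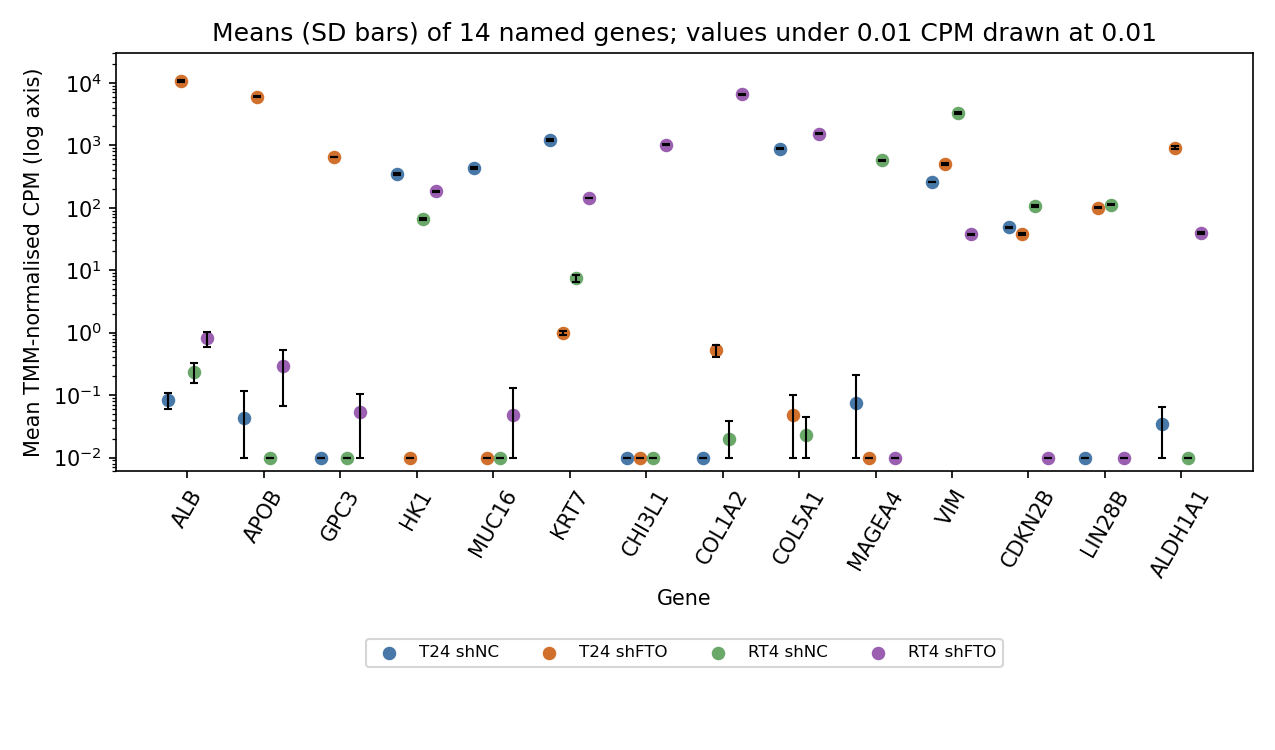
Mean TMM-normalised CPM (log axis) of 14 named genes in the 4 labelled groups (colours), with SD bars over 3 libraries and values under 0.01 CPM drawn at 0.01. ALB and APOB stand at 10700 and 6008 CPM in T24 shFTO and below 1 CPM in the other 3 groups, and COL5A1 is high in T24 shNC (879 CPM) and RT4 shFTO (1541 CPM).

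In RT4, 22 of 39 lists were called by camera (20 up, 2 down), and 4 held with an estimated correlation: mitosis, replication, NRF2 targets, and glycolysis and hypoxia. Mitosis genes rose for 40 of 40 members (40 adjusted over the list alone), with a median of 1.13 (camera BH-adjusted p = 7.88e-13, adjusted p = 0.0119 with an estimated correlation). MKI67, the proliferation antigen Ki-67, went from 73.0 ± 1.14 to 905 ± 35.7 CPM, and TOP2A (topoisomerase II alpha) changed by 2.34. Replication genes rose for 39 of 40 and fell for 1, the same adjusted over the list alone (median 1.35, camera BH-adjusted p = 1.2e-11, adjusted p = 0.0224 with an estimated correlation), among them CDC6 (an origin licensing factor) by 2.82 and RRM2 (a ribonucleotide reductase subunit) by 2.46. NRF2 targets rose for 25 of 27 and fell for 1, also adjusted over the list alone (median 1.73, camera BH-adjusted p = 1.01e-10, adjusted p = 0.0119 with an estimated correlation), with ABCC3, an organic anion exporter, from 1.46 ± 0.220 to 857 ± 2.23 CPM. Glycolysis and hypoxia genes rose for 31 of 36 and fell for 5, as adjusted over the list alone (median 1.64, camera BH-adjusted p = 1.23e-10, adjusted p = 0.0224 with an estimated correlation). VEGFA, an angiogenic growth factor, rose by 2.44 and NDRG1, a hypoxia-induced gene, by 5.81.

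Matrix-related lists rose together in RT4. Mesenchymal and EMT genes rose for 22 of 32 and fell for 6 (median 3.32, camera BH-adjusted p = 8.26e-06, adjusted p = 0.0928 with an estimated correlation), extracellular matrix and integrin genes for 28 of 39 with 9 down (median 1.71, camera BH-adjusted p = 3.74e-06, adjusted p = 0.172 with an estimated correlation), and TGF-beta response genes for 19 of 23 with 3 down (median 2.57, camera BH-adjusted p = 2.7e-05, adjusted p = 0.0834 with an estimated correlation). TGFBI, an extracellular matrix protein, went from 32.4 ± 1.20 to 3747 ± 135 CPM and FN1 (fibronectin) from 176 ± 1.96 to 4554 ± 123 CPM, whereas VIM (vimentin, a mesenchymal filament protein) went from 3313 ± 144 to 37.6 ± 0.527 CPM. Fibroblast markers moved with these lists, 9 of 11 up and 2 down (median 10.55, camera BH-adjusted p = 0.00038, adjusted p = 0.237 with an estimated correlation), and COL1A1, COL1A2, COL3A1 and POSTN stand in both the fibroblast and the EMT list. Antigen presentation genes rose for 22 of 22 (median 3.72, camera BH-adjusted p = 1.01e-10, adjusted p = 0.0928 with an estimated correlation) and interferon-stimulated genes for 28 of 38 with 5 down (median 1.30, camera BH-adjusted p = 5.96e-05, adjusted p = 0.0928 with an estimated correlation). B2M (the class I light chain) went from 169 ± 3.90 to 1728 ± 60.9 CPM. Adjusted over the list alone, the counts of these 6 lists were the same.

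Drug efflux and detoxification genes rose for 21 of 26 and fell for 4 (median 4.24, camera BH-adjusted p = 3.07e-06, adjusted p = 0.15 with an estimated correlation), with GSTM3, a glutathione transferase, from 0.161 ± 0.0197 to 72.3 ± 0.735 CPM. Unfolded protein response genes rose for 23 of 27 and fell for 2 (median 0.93, camera BH-adjusted p = 3.45e-06, adjusted p = 0.0928 with an estimated correlation), with CALR, an ER chaperone, up by 1.63. Cholesterol synthesis genes rose for 20 of 24 and fell for 2 (median 0.69, camera BH-adjusted p = 5.23e-05, adjusted p = 0.103 with an estimated correlation). The NF-kB list rose for 21 of 31 with 6 down (median 1.62, camera BH-adjusted p = 0.00442, adjusted p = 0.188 with an estimated correlation), and basal and squamous genes for 14 of 21 with 3 down (median 3.93, or 2.26 at the bounds, camera BH-adjusted p = 0.00853, adjusted p = 0.188 with an estimated correlation). The counts of these 5 lists were the same adjusted over the list alone. The 13 mitochondrial-genome-encoded mRNAs all rose (13 adjusted over the list alone, median 0.81, camera BH-adjusted p = 0.00853, adjusted p = 0.428 with an estimated correlation). In T24 the list did not pass, with 11 of 13 up and 0 down, as adjusted over the list alone (median 0.88, camera BH-adjusted p = 0.0672). It was called there without a low-count filter (0.00161), with the batch number as a block (0.0116), without any 1 of the RT4 libraries (0.00452 to 0.0469) and without T24 shFTO replicate 1 (0.0483). Fatty acid synthesis, DNA repair, autophagy and Wnt target genes were the other lists called up. Of their members 18 of 25, 25 of 38, 22 of 36 and 14 of 22 rose and 6, 12, 10 and 6 fell, the same adjusted over the list alone, with camera BH-adjusted p of 0.00783, 0.00974, 0.0123 and 0.0358, and adjusted p of 0.0928, 0.198, 0.269 and 0.188 with an estimated correlation. The Wnt call was lost with the batch number as a block (camera adjusted p = 0.0532) and with a filter of 1 CPM in 3 libraries (0.0503).

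Cytosolic ribosomal protein genes fell in RT4 for 44 of 52 and rose for 4, against 44 and 5 adjusted over the list alone (median -0.66, camera BH-adjusted p = 6.28e-06, adjusted p = 0.481 with an estimated correlation). The ATF4 and amino acid response list fell for 24 of 34 and rose for 7, the same adjusted over the list alone (median -0.76, or -0.72 at the bounds, camera BH-adjusted p = 0.000321, adjusted p = 0.172 with an estimated correlation). MTHFD2, a mitochondrial folate enzyme, went from 198 ± 4.49 to 0.143 ± 0.0571 CPM, and CBS, of the transsulfuration pathway, changed by -6.94. Stemness-associated genes did not pass, with 14 of 28 up and 9 down, as adjusted over the list alone (median 0.67, camera BH-adjusted p = 0.176). NES (nestin) went from 1.24 ± 0.361 to 130 ± 1.76 CPM and ALDH1A1 from 0 counts to 39.0 ± 1.37 CPM, while LIN28B fell to 0. The m6A list (6 up, 14 down of 24, camera BH-adjusted p = 0.106) and the luminal list (9 up, 7 down of 21, 0.645) did not pass, nor did leukocyte, endothelial and neuronal markers (0.307, 0.162 and 0.646). The m6A list was called down without a low-count filter (camera adjusted p = 0.00522) and with upper-quartile scaling (0.0413). Of the m6A list, ZCCHC4, VIRMA, YTHDF3 and IGF2BP1 changed by -2.49, -1.18, -1.09 and -1.24 on the log2 scale.

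**Figure D4:**
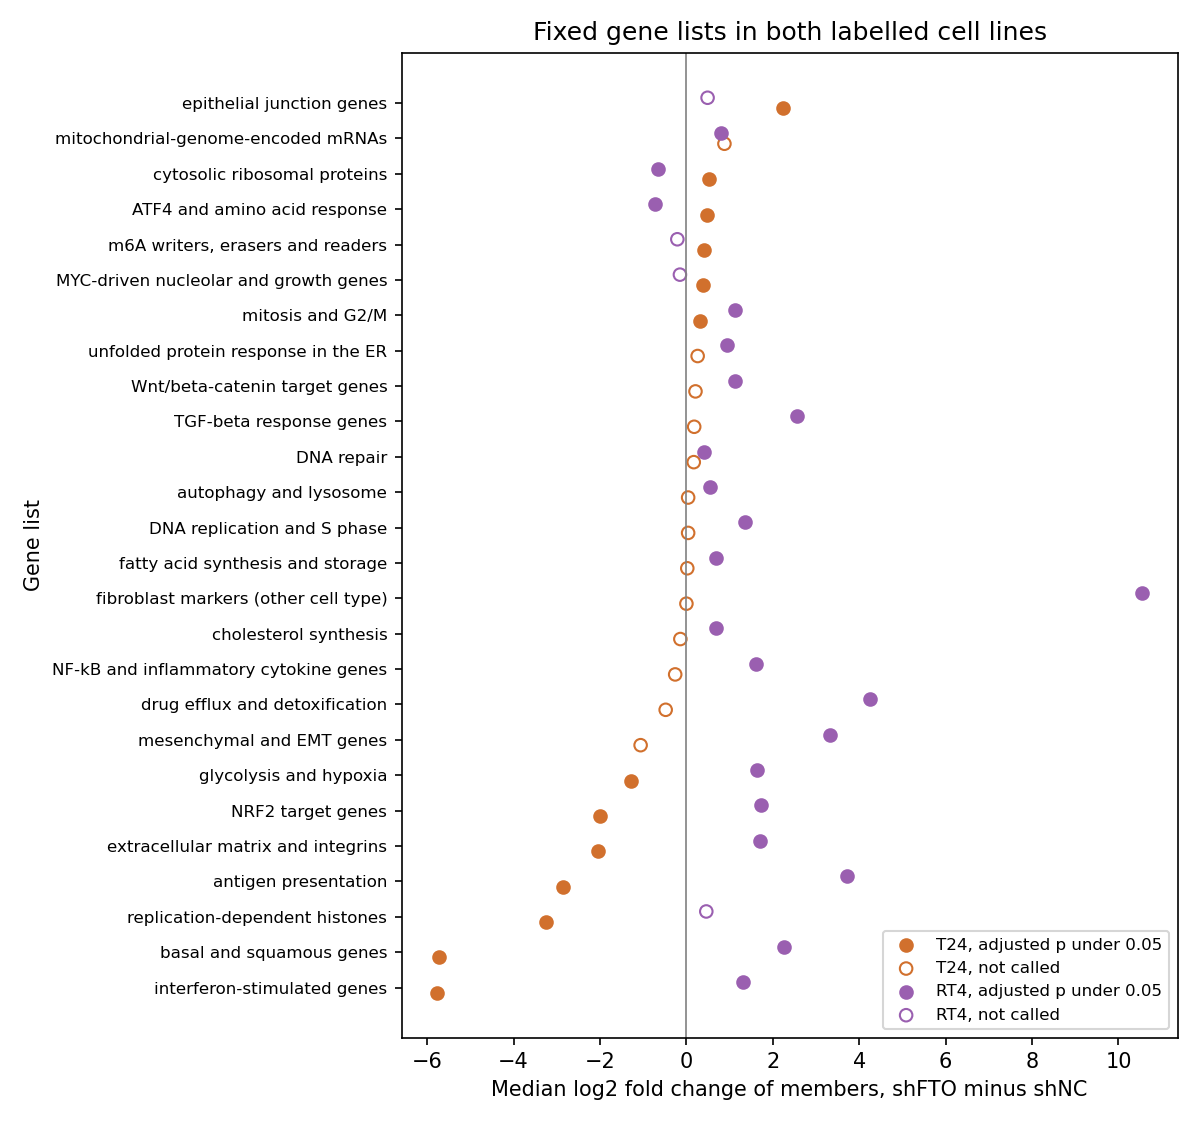
Median log2 fold change (x axis, shFTO minus shNC, members at 0 counts set to their bound) of the 26 lists called in at least 1 labelled line, in T24 (orange) and RT4 (purple). Filled points have a camera BH-adjusted p under 0.05; interferon-stimulated genes stand at -5.77 in T24 and 1.30 in RT4.

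The design text of the series names changes shared by both lines. Genes that rose in both and moved most included ALDH1A1, the chemokines CXCL12 and CXCL5, GABRA2 (a GABA receptor subunit), HJV (an iron regulator), SLC17A9 (a vesicular nucleotide transporter), SERPINA5 (a protease inhibitor), BHMT2, C6orf141 and PCDHGB5. CXCL12 was at 0 counts in both control groups and at 30.5 ± 1.67 and 72.3 ± 1.95 CPM in the libraries labelled T24 and RT4 shFTO. TDRD9, MUC15, KCNH5 (a potassium channel), SULT4A1 (a sulfotransferase), RNF212 (a meiotic recombination protein), JHY, SPINK5 (a protease inhibitor of skin), RHOXF2 (a homeobox gene of the germline), KCNG1 and HOXC-AS2 fell in both. TDRD9 went from 54.5 ± 1.31 CPM in T24 and 145 ± 3.70 CPM in RT4 to 0 counts in both. Over these 20 genes the highest edgeR BH-adjusted p was 6.34e-10. PCDHGB5 lies in a cluster with shared exons, RHOXF2 has a near copy and HOXC-AS2 is antisense, so their counts are uncertain.

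Of 23070 genes, 6685 were called in the same direction in both lines (3226 up and 3459 down) and 7813 in opposite directions. Independent lists of these sizes would share 3314 up and 3764 down, so fewer were shared than that. One-sided Fisher exact tests for an excess gave p = 0.993 and p = 1. Fisher exact tests for a departure in either direction gave p = 0.0138 for genes up in both and p = 6.45e-17 for genes down in both. In opposite directions, 3790 genes rose in T24 and fell in RT4 against 3430 for independent lists, and 4023 did the reverse against 3638. For these, one-sided Fisher exact tests gave p = 8.21e-24 and p = 2.03e-26. In all these tests genes are not independent replicates. Across genes the log2 changes of both lines had Pearson r = -0.104 and Spearman rho = -0.08, and r within batches 1, 2 and 3 was -0.111, -0.109 and -0.107. At a change of at least 2-fold in both lines, 2840 genes shared their direction and 3557 went in opposite directions. All these directions follow the RT4 labels, which FTO went against. With shFTO and shNC exchanged in RT4, shared and opposite counts would trade places, the excess would lie with shared genes, and r and rho would be positive. The counts therefore do not show opposed responses to FTO knockdown.

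The interaction asks which changes differed between the lines, T24 minus RT4. LIN28B went from 0 counts to 99.5 ± 1.80 CPM in T24 and from 112 ± 1.58 CPM to 0 counts in RT4, and ZNF667, its antisense partner ZNF667-AS1, ZNF135 (zinc finger genes) and UCHL1 had the same pattern, with 0.131 ± 0.144 CPM of UCHL1 in T24 shNC. FENDRR, CDH13, SLCO3A1 (an organic anion transporter) and CES1 (a carboxylesterase) went from 68.0 ± 3.64, 41.2 ± 1.01, 79.2 ± 1.22 and 36.6 ± 1.73 CPM to 0 counts in T24, and from 0 counts to 190 ± 2.11, 156 ± 0.543, 64.4 ± 2.78 and 57.3 ± 2.13 CPM in RT4. COL5A1 fell in T24 from 879 ± 18.6 to 0.0472 ± 0.0517 CPM and rose in RT4. Over these 10 genes the highest edgeR BH-adjusted p of the difference was 6.64e-14. Counts of ZNF667 and ZNF667-AS1 are uncertain where the strand setting is not known. In all, 17298 genes (75.0%) differed, 8376 with the higher change in T24 and 8922 with the higher change in RT4. Of 39 lists, 19 were called for the difference by camera, 4 with the higher change in T24 and 15 with the lower, and 2 held with an estimated correlation. These 2 were NRF2 targets (camera BH-adjusted p = 2.91e-11, adjusted p = 0.00328 with an estimated correlation) and glycolysis and hypoxia (4.82e-11, and 0.0317 with an estimated correlation). Lists called by the preset test only included interferon-stimulated genes (1.53e-13, and adjusted p = 0.12 with an estimated correlation) and antigen presentation (5.07e-11, and adjusted p = 0.126 with an estimated correlation). The stemness list was not called (camera BH-adjusted p = 0.732).

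The controls, T24 shNC against RT4 shNC, compare the lines as labelled before any knockdown. Whether these libraries hold the labelled lines is left open below. MUC16, UGT1A7, TRIM29 (a basal epithelial gene) and SIK1 (a salt-inducible kinase) were at 432 ± 15.2, 410 ± 21.98, 395 ± 8.51 and 227 ± 5.75 CPM in T24 shNC and at 0 counts in RT4 shNC, at least 34950-, 33350-, 32130- and 18510-fold higher. KRT17 (a basal keratin) was at 1264 ± 46.1 CPM in T24 shNC and had 3 counts over the RT4 shNC libraries, a ratio of 103100 with a 95% counting interval from 35270 to 499800. LIN28B, ZSCAN18 (a zinc finger gene), CCNYL2, FAM9C and TMEM200A were at 67.4 to 128 CPM in RT4 shNC and at 0 counts in T24 shNC, at least 2607- to 4967-fold higher. The highest edgeR BH-adjusted p of these 10 genes was 6.6e-08. In all, 18475 genes (80.1%) were called, 9305 higher in T24 and 9170 higher in RT4.

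Of the lists for epithelial state, basal and squamous genes were higher in T24 shNC for 17 of 21 members and lower for 3, also adjusted over the list alone (median 8.21, or 5.89 at the bounds, camera BH-adjusted p = 6.83e-05, adjusted p = 0.232 with an estimated correlation). Luminal urothelial genes were higher for 15 of 21 and lower for 4 (median 2.76, camera BH-adjusted p = 0.00477, adjusted p = 0.123 with an estimated correlation), with KRT8, a luminal keratin, at 3765 ± 90.8 against 168 ± 5.98 CPM. Epithelial junction genes were higher for 21 of 29 and lower for 5 (median 3.14, or 2.87 at the bounds, camera BH-adjusted p = 0.00678, adjusted p = 0.346 with an estimated correlation), with DSP (desmoplakin) at 325 ± 6.85 against 3.33 ± 0.342 CPM. Mesenchymal and EMT genes did not pass (15 higher, 13 lower of 32, camera BH-adjusted p = 0.383), and VIM was at 260 ± 0.549 CPM in T24 shNC and 3313 ± 144 CPM in RT4 shNC. The last 3 lists had the same counts adjusted over the list alone. Luminal and junction genes were thus mostly lower, and VIM higher, in the group labelled RT4, the line from the well-differentiated tumour. No reason for this was tested. In all, 17 lists were called (16 higher in T24), and 2 held with an estimated correlation, replication (adjusted p = 0.0399) and NRF2 targets (adjusted p = 0.0195).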

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

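All tests of the 3 patterns below were chosen after the results were seen, and the counts of other splits were planned. What brings these results here is a difference between the lines in the response to the shFTO label, tested as an interaction by edgeR.

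For 17298 of 23070 genes the change differed between the lines. FTO itself differed by -1.04 (log2, T24 change minus RT4 change). The largest differences among named genes were LIN28B 30.7, ZNF667-AS1 27.05, ZNF667 25.91, UCHL1 25.88 and ZNF135 25.59 on one side, and FENDRR -30.91, CDH13 -29.91, COL5A1 -29.66, SLCO3A1 -29.57 and CES1 -28.29 on the other. These fitted values depend on the prior count where a group has 0 counts. Of 258 named genes, 222 had changes that differed between the lines.

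The groups of 1 labelled line differed from each other about as much as groups of different lines. Knockdown of the FTO transcript in the RT4 libraries is argued against by its log2 change of 0.58 (SE 0.045), if both RT4 groups are 1 cell line. If they are not, RT4 shNC is no baseline for RT4 shFTO, and this change cannot show whether FTO was knocked down. The same limit holds in T24, where FTO changed by -0.46 and the groups correlated less, at 0.706. If the T24 groups are not 1 cell line, that fall cannot show a knockdown either. For depth, genes above 10 CPM in one group and under 0.1 CPM in the other were counted before and after thinning. They numbered 520 before and 520 after in T24, and 406 before and 416 after in RT4. The smallest library holds 31291047 counts, so a gene above 10 CPM keeps many reads after thinning. The number could hardly fall, and thinning therefore does not test depth. FTO knockdown in 1 unchanged cell line in T24 (r = 0.706 between its groups), 2 cell lines with group labels exchanged (r = 0.709 for T24 shFTO with RT4 shNC, the partner of the closest pair) and 4 different cell populations (r = 0.761 between the RT4 groups) stay open. Genes above 10 CPM in one group and under 0.1 CPM in the other numbered 439 between the controls and 540 between the shFTO groups. They numbered 287 for T24 shNC with RT4 shFTO, 522 for T24 shFTO with RT4 shNC, and at most 4 between replicates. None of the 3 ways to pair the groups, the labelled one included, had both of its pairs above every other pair in r. A knockdown response sets no bound on r or on such genes, and no genotype was measured. The accounts left open therefore cannot be told apart.

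In the RT4 libraries labelled shFTO, 5 neighbouring expressed genes on chromosome 9 (21329665 to 22455740) were at or near 0: KLHL9, MTAP, CDKN2A (p16 and p14ARF), CDKN2B and DMRTA1. CDKN2A went from 70.4 to 0.053 CPM, while the flanking genes FOCAD, CAAP1 and PLAA were at 66.17, 14.06 and 44.88 CPM (45.78, 25.98 and 38.82 in shNC), and HACD4 and TUSC1, which lie between, at 0.6996 and 1.264 CPM (0.2139 and 0.007361). Chance neighbours among silent genes are argued against, since 0 of 10000 random gene orders had a run as long. Loss of a stretch of DNA, which would cover all 5 genes, stays open and cannot be told apart from silencing, because RNA alone was measured and 5 runs were at least that long, among them HOX and zinc finger clusters. No biological explanation was tested.

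Liver-type transcripts were abundant in the T24 libraries labelled shFTO, with 21 of 23 tested hepatocyte markers at 10 CPM or more. Liver-type cells mixed with cells like the T24 shNC libraries are argued against by 90 genes, out of 2077 at 100 CPM or more in T24 shNC, that stood under 1% of that level in each shFTO library. Liver-type cells as the source of the T24 shFTO libraries stay open, as does induction of these genes by the shRNA. The 21 markers would be high in either case and no genotype was measured, so these cannot be told apart. Other values also set the T24 groups apart. T24 shFTO correlated with T24 shNC at a mean r of 0.706 and with RT4 shNC at 0.709. HOXB, HOXC and HOXD genes at 1 CPM or more numbered 9, 8 and 4 in T24 shNC and 0, 0 and 0 in T24 shFTO, while HOXA had 9 in both.

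For genes called in T24, RT4 and between the controls, only 10 splits exist, too few for a share under 0.05, and 1 of 10, the real one, had as many calls (18006, 18124 and 18475, and 0 at most for the others by edgeR, where up to 319, 367 and 273 genes had an unadjusted p under 0.05). For lists, again 1 of 10 had as many, with 13, 22 and 17 in the real split and up to 11, 21 and 14 in mixed ones. Each mixed split still has unequal numbers of libraries of the real groups on each side, so part of the real difference remains. These counts therefore cannot show how many lists would be called by chance. For the difference between lines, 1 of 40 splits, the real one, had as many calls, 17298 against at most 6832 in the random draws. These draws mix shFTO with shNC libraries within a line, which widens the spread and lowers the calls. The labels thus group like libraries, but the draws do not test whether the response differed between the lines. For calls in the same and in opposite directions 1 of 40 splits, again the real one, had as many, 6685 and 7813 against 0 and 0 by edgeR. A draw that mixes either line calls 0 genes in that line, so these counts add nothing.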

How the results depend on the processing

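The alternatives were chosen before the data were examined, except thinning to the smallest library and library totals as the only scaling for FTO. Apart from the 2-fold threshold, calls over the alternatives and leave-one-out fits ranged from 15416 to 19288 in T24, 15391 to 19785 in RT4, 6012 to 6790 in the same and 6953 to 7927 in opposite directions, 14997 to 18641 for the interaction and 15581 to 20437 between controls, within 1.5 times the values reported. The 2-fold threshold by construction left 11242, 11073, 2840, 3557, 12765 and 11792. FTO kept its direction and its call in all, from -0.644 to -0.423 in T24 and from 0.308 to 0.616 in RT4 on the log2 scale. With an estimated correlation camera called 0 lists in T24 (6 at an unadjusted p under 0.05), 4 in RT4 and 2 between controls, and fry called 39, 37 and 39. Leaving out each library gave 12 to 14, 22 to 22 and 16 to 19 lists. The correlation across genes stayed negative: -0.072 with no filter, -0.116 with 1 CPM in 3 libraries, -0.102 with limma-voom, -0.14 with each line alone, -0.107 after thinning, -0.167 at a mean of 1 CPM in each line, and -0.102 to -0.098 in leave-one-out fits. The cause was not tested. Each sign rests on the RT4 labels: with shFTO and shNC exchanged there, every value would be positive. The batch number as a block gave 17444, 17493, 16641 and 17818 calls (T24, RT4, interaction, controls), of which 17347, 17412, 16574 and 17726 were shared with the fit without it, with 6307 genes in the same and 7408 in opposite directions. It gave 12, 21 and 16 lists: in T24 the matrix and ATF4 lists lost their call and mitochondrially encoded mRNAs gained one (adjusted p = 0.0116), in RT4 the Wnt list lost its call, and between controls the cholesterol (0.056) and NF-kB (0.123) lists lost theirs and histones gained one (0.0465). Of 7760 recomputed values of named genes, 7758 kept their direction and call. ROBO4 in lines (controls, -0.30, not called) was 0.031 without T24_shNC replicate 3, -0.698 without T24_shNC replicate 1 and 0.012 after thinning, and the cause was not tested. Thinning to the smallest library gave 17374 calls in T24 and 17188 in RT4.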

Other observations

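All lists and tests in this part were chosen after the data were seen, so they describe these libraries and test nothing.

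Hepatocyte genes other than those named above were high in the T24 libraries labelled shFTO. Transcripts of APOA2 (an apolipoprotein of high-density lipoprotein), AHSG (fetuin A), TF (transferrin) and SERPINA1 (alpha-1 antitrypsin) stood at 4649, 3067, 2493 and 1578 CPM there. Summed over the marker list, hepatocyte transcripts came to 32720 CPM in T24 shFTO, against 147 in T24 shNC, 9.594 in RT4 shNC and 41.21 in RT4 shFTO. Of the markers, VTN (vitronectin) at 134.9 CPM was the only one at 10 CPM or more in T24 shNC, and SERPINA1 at 31.7 CPM the only one in RT4 shFTO.

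Cancer-testis genes, normally restricted to the germline, were at 10 CPM or more for 11 of 17 tested genes in RT4 shNC, against 0 in RT4 shFTO, 0 in T24 shFTO and 2 in T24 shNC. MAGEA4, TDRD9, PRAME and CTAG1B stood at 579.6, 145.5, 131.9 and 118.0 CPM in RT4 shNC. HOX clusters, which keep a record of body position, also differed by group. HOXC genes at 1 CPM or more numbered 8 of 8 in T24 shNC, 0 in T24 shFTO, 6 in RT4 shNC and 0 in RT4 shFTO. For HOXA the numbers were 9, 9, 8 and 0 of 11, for HOXB 9, 0, 8 and 5 of 9, and for HOXD 4, 0, 3 and 3 of 7, in the same order.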
